A study of Mus musculus with 14 samples.

How the data were processed

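RNA of blood monocytes was measured on 14 single-channel Affymetrix mouse arrays, 1 array per sort, with biotin label and an extended in vitro transcription per the labels. The arrays fell into 4 groups given by the labels: Ly6Chi and Ly6Clo monocytes of control mice (4 arrays each) and of mice given rosiglitazone for 1 week (3 arrays each), each sort from the pooled leukocytes of 5 mice. The values deposited by the authors were on a log2 scale, from 3.61 to 15.2, and array medians lay between 6.70 and 6.80. GCRMA was the tool named per the submitters' processing notes, with no version and no statement of its role. The values were used as deposited, with no further scaling. Their precision was limited by the number of arrays.

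The table held 45101 probe sets, of which 64 were control probe sets. In the annotation given, 34958 had 1 gene symbol, 932 had several and 9211 were not listed. Of the symbols, 34754 were matched by gene identifier and 0 changed. A probe set was kept when it was above the array median on at least 3 arrays, which left 24531, of which 20829 had 1 symbol. Each gene was represented by the probe set with the highest mean over all arrays, which gave 12104 genes, 5214 of them with several probe sets. Probe sets with no single symbol were tested apart and not named.

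A linear model of the 4 group means was fitted to all 14 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 10 residual degrees of freedom and no block. There were 6 contrasts: Ly6Clo against Ly6Chi in control mice and in rosiglitazone mice, rosiglitazone against control in Ly6Chi and in Ly6Clo monocytes, the average of the last 2, and their difference. P values were adjusted by Benjamini-Hochberg over the 12104 genes in each contrast, and a gene passed at adjusted p under 0.05. Errors are standard errors of the log2 fold change. They rest on a spread per gene shared by all 14 arrays, so those within a subset also hold the spread of the other. The agreement of 2 contrasts was given as the Pearson and Spearman correlation of the log2 fold changes across genes, with the count of genes called in both against the count expected by chance.

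Groups of genes were tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over the 24 lists in each contrast, and again with the correlation estimated per list. The lists were fixed before the data were examined, as were the contrasts, tests, filter and alternatives. They were PPAR target genes, PPAR, RXR and coregulators, LXR target and lipogenic genes, cholesterol synthesis, oxidative phosphorylation, glycolysis, Ly6Chi monocyte markers, Ly6Clo monocyte markers, cell cycle, inflammatory and NF-kB genes, interferon-stimulated genes, MHC class II and costimulation, alternative activation, scavenger, Fc and efferocytosis receptors, adhesion and chemokine receptors, immediate early and heat shock genes, and circadian and glucocorticoid-responsive genes. The other 7 held markers of neutrophils, B cells, T and NK cells, platelets, red cells, dendritic cells, and eosinophils, basophils and mast cells. They held 418 different genes, of which 381 were in the annotation and 329 were tested. Counts of list members that passed are given over all genes tested and, where these differ, adjusted over the list alone. With the estimated correlation, 7 of the 47 list calls held: Ly6Chi markers, Ly6Clo markers and cell cycle between subsets in control mice, Ly6Chi and Ly6Clo markers in rosiglitazone mice, and PPAR target genes and inflammatory genes in the difference of the rosiglitazone effect.

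Genes were named by a rule: up to 10 genes per direction and contrast with the largest fold change among those that passed and whose groups of arrays did not overlap, up to 4 members of each list with the smallest p, and a fixed set of monocyte and PPAR genes. The sort marker genes were not reported as a finding.

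In simulated data, limma recovered a log2 change of 1 for 89.6% of genes between subsets in control and 86.6% in rosiglitazone mice. It recovered 92.5% with rosiglitazone in Ly6Chi, 88.1% in Ly6Clo, 97.0% in the average and 73.1% in the difference. A change of 0.5 was recovered for 59.7%, 50.7%, 52.2%, 49.3%, 77.6% and 22.4%. False calls were 5.18% to 8.72% of all calls. For the difference, camera called 100% of lists of 20 genes shifted by 0.5 and 1% of unshifted lists. Simulated genes varied independently, so these rates do not hold for lists whose genes vary together. Nor need they hold for groups of unequal spread, as the treated groups were.

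The labels did not say that a replicate number marks a shared sort or day. Deviations of same-numbered arrays from their group means were therefore correlated. For the subsets in rosiglitazone mice r was 0.13, 0.33 and 0.28, and for rosiglitazone in Ly6Chi monocytes it was 0.22, 0.27 and 0.36, so by the rule set for this check the numbers paired the arrays in these 2 comparisons. For replicate 1 the best r with another number came close, at 0.094 for the subsets and 0.21 for rosiglitazone in Ly6Chi monocytes. The pairing rests on the data and not on the labels, and whether it could arise by chance was not tested. No 2 arrays were copies of one another, with a highest correlation of 0.996 and at most 0.0643% of values identical.

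The alternatives tried were the replicate number as a block, treatment and replicate number together as a block, quantile normalization, median centring, no filter, a filter at the array 70th percentile, the mean of a gene's probe sets, every probe set by itself, eBayes with trend and robust, array quality weights, a fit of the 2 compared groups alone, a further 2-fold minimum, the estimated correlation in camera, and leaving out each array in turn. Chosen after seeing the data was a fit with values under an array's lower quartile raised to it, since no detection measure was used: where the mean of a group lies under the quartile, it gives the difference as a bound. Hybridization spikes, poly-A spikes and the 3-prime and 5-prime probe sets of Actb and Gapdh were compared between the 8 control and 6 treated arrays by exact permutation over all 3003 splits. The spikes and the Actb value separated treated from control arrays, while the Gapdh values overlapped, with -0.03 to 0.192 on control and 0.139 to 0.416 on treated arrays (exact permutation p = 0.0017). Batch and treatment therefore cannot be told apart in the comparisons of rosiglitazone with control. The comparisons of subsets lie within control or within treated arrays, but the treated arrays of the 2 subsets did not overlap in the poly-A spikes (5.82 to 6.07 in Ly6Chi and 6.17 to 6.85 in Ly6Clo) or in the Gapdh value (0.139 to 0.188 and 0.266 to 0.416). The control arrays of the 2 subsets did not overlap in the Actb value (0.273 to 0.310 in Ly6Chi and 0.204 to 0.263 in Ly6Clo). The subset comparisons in both treatments and the difference of the rosiglitazone effect are therefore not free of processing. Chosen after seeing the data was a linear model of these measures on the 4 groups, with the difference of their changes between subsets.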

Results

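Expression was measured in blood monocytes of male mice that were 12 weeks old, sorted into the Ly6Chi subset, the inflammatory monocytes, and the Ly6Clo subset, the patrolling monocytes. Mice had received rosiglitazone, an agonist of the nuclear receptor PPARγ, for 1 week, or were controls. Each array held RNA of 1 sort from the pooled leukocytes of 5 mice, so replicates were separate sorts of pooled mice and not single mice. There were 4 arrays each of Ly6Chi and Ly6Clo monocytes from control mice, and 3 arrays each from rosiglitazone mice. The number of arrays limited the precision, with a median standard error of the log2 fold change of 0.115 for the subsets in control mice, 0.133 in rosiglitazone mice, 0.124 for rosiglitazone within a subset and 0.176 for the difference of its effect between subsets. The array medians lay between 6.70 and 6.80 on the log2 scale. On the first principal component, with 50.3% of the variance, the 2 subsets separated, and on the second, with 21.8%, the treated and control arrays separated.

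Control and treated arrays also differed in probe sets that do not measure the cells. The mean of the hybridization spikes was 12.4 to 13.5 on the 8 control arrays and 10.5 to 11.05 on the 6 treated arrays, a difference of -2.11 (exact permutation p = 0.000333). The poly-A spikes differed by -2.99 (exact permutation p = 0.000333). The difference between the 3-prime and 5-prime probe sets of Actb, a sign of RNA length, was 0.204 to 0.310 on control arrays and 0.395 to 0.903 on treated arrays (exact permutation p = 0.000333). In every comparison of rosiglitazone with control, batch and treatment cannot be told apart. The third principal component, with 14.95% of the variance, set apart replicate 3 of Ly6Chi monocytes from rosiglitazone mice, whose mean correlation with its group was 0.956 against 0.975 and 0.976 for the other 2. Each count of changed genes is therefore also given without that array.

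**Figure D1:**
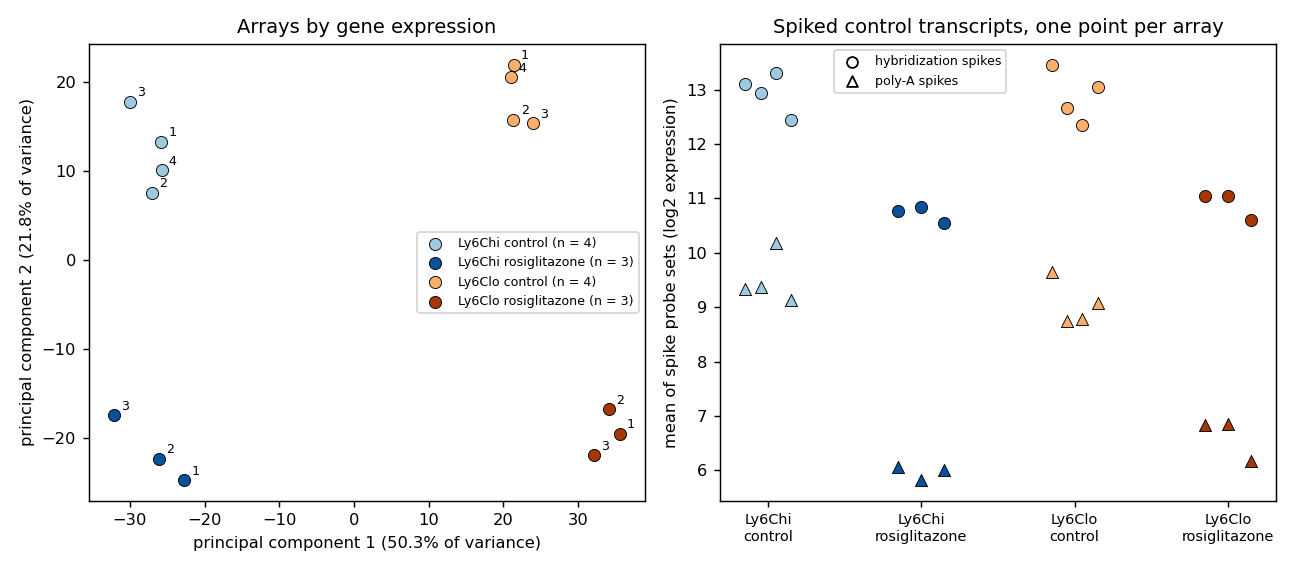
Left, the 14 arrays on the first 2 principal components, which held 50.3% and 21.8% of the variance, by subset and treatment. Right, the mean log2 signal of the hybridization and poly-A spikes on each array, which was lower on all 6 treated arrays.

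The first comparison asked how Ly6Clo and Ly6Chi monocytes differ in control mice. In the 3-prime minus 5-prime value of Actb the control arrays of the subsets did not overlap. That value was 0.273 to 0.310 in Ly6Chi and 0.204 to 0.263 in Ly6Clo monocytes. Fabp4, a fatty acid binding protein, was 20.2-fold higher in Ly6Clo monocytes (log2 fold change ± standard error 4.34 ± 0.17, adjusted p = 6.7e-10, 4 arrays per subset, 4 probe sets from 0.99 to 4.51), and the lymphatic growth factor gene Vegfc was at least 23.8-fold higher (4.85 ± 0.16). Other genes among the largest rises were the phosphatase gene Dusp16 (4.24 ± 0.14), the scavenger receptor gene Cd36 (4.23 ± 0.32), the ion transporter gene Slc12a2 (4.05 ± 0.19), Cd83 (3.66 ± 0.23), Ikzf3 (3.64 ± 0.23), Tgfbr3 (3.60 ± 0.15) and G0s2 (3.58 ± 0.16). Among the largest falls were those of Vcan, which encodes versican (-5.48 ± 0.43), the neutrophil surface protein gene Cd177 (-5.17 ± 0.12), the collagenase gene Mmp8 (-4.58 ± 0.20), Atrnl1 (-4.14 ± 0.20), the fibronectin gene Fn1 (-4.00 ± 0.12), Aplnr (-3.67 ± 0.22), Met (-3.47 ± 0.18), Slfn4 (-3.42 ± 0.24) and Sgms2 (-3.30 ± 0.16). The dimmer subset lay under the lower quartile of the arrays, 5.56 to 5.71, for Vegfc (5.32), Vcan (5.25) and Aplnr (5.19), so their differences are bounds of at least 4.57 for Vegfc and at most -5.14 for Vcan and -3.26 for Aplnr. Of 12104 genes tested with limma, 2688 passed, 1108 higher and 1580 lower in Ly6Clo monocytes, and for 2586 of these the arrays of the 2 subsets did not overlap. At least a 2-fold change was seen in 212 of the higher and 306 of the lower genes. Without the replicate that stood apart, 3951 genes passed, 1704 higher and 2247 lower, and all 2688 were among them.

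Of 16 tested Ly6Clo monocyte markers, 15 rose (median 1.74, camera adjusted p = 1.0e-23), and all 10 Ly6Chi markers fell (median -2.83, camera adjusted p = 2.0e-14). Both calls held with an estimated correlation, with adjusted p = 0.0053 and 0.019. Among the Ly6Clo markers were Itgax, which encodes CD11c (3.76 ± 0.13), and Treml4 (2.11 ± 0.08). Spn, which encodes CD43, was higher by 1.74 ± 0.14, Itgal by 0.95 ± 0.08 and Nr4a1, a nuclear receptor needed for Ly6Clo monocytes, by 0.93 ± 0.15. Among the Ly6Chi markers were F13a1, a clotting factor gene (-3.65 ± 0.15), and the chemokine receptor gene Ccr2 (-1.50 ± 0.13). The fractalkine receptor gene Cx3cr1 did not pass (0.29 ± 0.21, adjusted p = 0.41). Of 21 cell cycle genes, 8 rose and 2 fell (10 and 2 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 6.6e-04), a call that held with an estimated correlation (adjusted p = 0.019). Mcm5 (1.49 ± 0.18), Mcm6 (1.44 ± 0.12) and Mcm7 (1.04 ± 0.14), which encode parts of the replicative helicase, were among those that rose, as was Rrm1, which encodes a subunit of ribonucleotide reductase (1.10 ± 0.11). The mean level of the proliferation marker gene Mki67 went the other way, at 6.44 ± 0.11 (SD) in Ly6Clo and 7.04 ± 0.18 (SD) in Ly6Chi monocytes.

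Interferon-stimulated genes were lower in Ly6Clo monocytes, where 18 of 19 fell, or 19 over the list alone (median -1.01, camera adjusted p = 1.1e-16, and adjusted p = 0.089 with an estimated correlation). Ifit1 (-2.30 ± 0.21), Ifit2 (-2.37 ± 0.21), Ifit3 (-1.91 ± 0.15) and Usp18 (-2.25 ± 0.13) were among them. Of 13 genes of MHC class II and costimulation, 6 rose and 1 fell, or 7 and 1 over the list alone (median 0.84, camera adjusted p = 2.1e-04, and adjusted p = 0.12 with an estimated correlation), with H2-Eb1 at 1.78 ± 0.14, H2-Ab1 at 1.35 ± 0.12 and H2-Aa at 0.84 ± 0.10. Of 21 adhesion and chemokine receptor genes, 9 rose and 3 fell, or 9 and 4 over the list alone (median 0.29, camera adjusted p = 3.9e-04, and adjusted p = 0.12 with an estimated correlation). S1pr5, a sphingosine phosphate receptor gene, was at 2.87 ± 0.22 and Pecam1, which encodes CD31, at 1.97 ± 0.15. Circadian and glucocorticoid-responsive genes had 5 of 14 members higher and 1 lower (median 0.12, camera adjusted p = 0.0065, and adjusted p = 0.25 with an estimated correlation), led by Bhlhe40 (2.53 ± 0.17) and Zbtb16 (1.88 ± 0.18). Single members of lists that were not called changed as well, such as Il1b (1.69 ± 0.25), the scavenger receptor gene Msr1 (-1.46 ± 0.15) and Cxcl10 (-2.55 ± 0.23). The Fc receptor gene Fcgr4 (2.91 ± 0.19) and Chil3 (-2.96 ± 0.25) belong to such lists too, but also to the called Ly6Clo and Ly6Chi marker lists.

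Pparg itself was 7.83-fold higher in Ly6Clo monocytes of control mice (2.97 ± 0.20, adjusted p = 1.3e-07). Its target genes did not move together, since 3 of 24 rose and 7 fell, or 4 and 8 over the list alone. The median of that list was -0.08, its mean 0.25 and the direction of its test down (camera adjusted p = 0.64). Fabp4, Cd36 and the transglutaminase gene Tgm2 (3.47 ± 0.16) were the 3 that rose. The lipase gene Lpl (-2.17 ± 0.20) and Cpt1a, which encodes the enzyme that admits fatty acids to mitochondria (-0.43 ± 0.08, adjusted p = 0.0017), were among those that fell. With the mean of its probe sets the call of Cpt1a was lost (adjusted p = 0.18). Angptl4 (-0.11 ± 0.13, adjusted p = 0.68) and Plin2 (0.27 ± 0.09, adjusted p = 0.051) did not pass. Of 14 LXR target and lipogenic genes, 10 rose and none fell, or 11 over the list alone (median 0.51, camera adjusted p = 9.9e-06, and adjusted p = 0.10 with an estimated correlation), among them Pltp (1.34 ± 0.16), Apoe (0.84 ± 0.11) and Apoc2 (0.90 ± 0.13). Cholesterol synthesis genes had 5 of 18 members higher and 1 lower, or 7 and 1 over the list alone (median 0.31, camera adjusted p = 0.0034, and adjusted p = 0.63 with an estimated correlation), with Sqle at 0.93 ± 0.25. Of 26 genes of oxidative phosphorylation, 12 fell, or 14 over the list alone (median -0.25, camera adjusted p = 2.1e-04, and adjusted p = 0.46 with an estimated correlation), with Ndufb5 at -0.49 ± 0.07.

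Markers of other cell types also differed between the sorted subsets of control mice. Of 11 neutrophil markers, 4 were lower in Ly6Clo monocytes, or 5 over the list alone (median -0.47, camera adjusted p = 0.0044, and adjusted p = 0.12 with an estimated correlation), among them Cd177, Lcn2 (-1.86 ± 0.43) and Csf3r (-0.51 ± 0.13). Of 13 T and NK cell markers, 2 were higher (median 0.15, camera adjusted p = 0.033, and adjusted p = 0.35 with an estimated correlation), with Klrd1 at 1.98 ± 0.31. The T and NK cell call was lost without Ly6Chi control replicate 4 (adjusted p = 0.061), without Ly6Clo control replicate 1 (adjusted p = 0.10) and with quantile normalization (adjusted p = 0.057), and its median ranged from 0.088 to 0.20 with single arrays left out.

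The same comparison in rosiglitazone mice asked how the subsets differ under the drug. The treated arrays of the 2 subsets also did not overlap in the poly-A spikes (5.82 to 6.07 in Ly6Chi and 6.17 to 6.85 in Ly6Clo) or in the 3-prime minus 5-prime value of Gapdh (0.139 to 0.188 and 0.266 to 0.416). Fabp4 was 74.2-fold higher in Ly6Clo monocytes (6.21 ± 0.20, adjusted p = 1.0e-10, 3 arrays per subset, 4 probe sets from 2.22 to 6.21), followed by Vegfc (5.69 ± 0.19), Cd36 (5.42 ± 0.37), Dusp16 (4.85 ± 0.16), G0s2 (4.76 ± 0.18), Tgfbr3 (4.64 ± 0.18) and Itgax (4.55 ± 0.15). Ets1 (4.50 ± 0.36), the muscle enolase gene Eno3 (4.48 ± 0.22) and Slc12a2 (4.32 ± 0.22) completed the 10 largest rises. The 10 largest falls were in Cd177 (-5.10 ± 0.14), Vcan (-4.83 ± 0.49), Fn1 (-4.48 ± 0.14), Mmp8 (-4.16 ± 0.24), Atrnl1 (-3.96 ± 0.23), Capg (-3.96 ± 0.21), F13a1 (-3.90 ± 0.17), Anxa3 (-3.80 ± 0.24), Gas7 (-3.76 ± 0.19) and Tfec (-3.68 ± 0.36). Vegfc in Ly6Chi (5.35) and Vcan (5.22) and Tfec (4.78) in Ly6Clo monocytes lay under the lower quartile of the arrays, so their differences are bounds of at least 5.38, at most -4.42 and at most -2.84. With limma, 3198 genes passed, 1875 higher and 1323 lower, of which 377 and 366 changed at least 2-fold, and for 3056 the arrays did not overlap. Without the replicate that stood apart, 3721 passed, 1611 higher and 2110 lower, with 2782 of the 3198 kept. The share of higher genes, 58.6%, depended on the scaling. Quantile normalization gave 1856 higher and 1989 lower genes (48.3%), and median centring gave 1652 and 1996 (45.3%) and moved the median of all genes from 0.05 to -0.06. A fit of these 2 groups alone called 1544 genes.

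PPAR target genes were higher in Ly6Clo monocytes of rosiglitazone mice, where 12 of 24 rose and 3 fell, or 13 and 3 over the list alone (median 0.44, camera adjusted p = 1.2e-04, and adjusted p = 0.13 with an estimated correlation). With single arrays left out the median ranged from 0.29, without Ly6Chi rosiglitazone replicate 3, to 0.62, and the call held. Besides Fabp4 and Cd36, those higher were Tgm2 (3.89 ± 0.19), Angptl4, an inhibitor of lipoprotein lipase (1.74 ± 0.15), and the lipid droplet protein gene Plin2 (1.54 ± 0.11), among others. Cpt1a was at 0.37 ± 0.10, adjusted p = 0.012, and adjusted p was 0.057 with the mean of its probe sets. Pparg was 8.07-fold higher (3.01 ± 0.24). Of 14 LXR target and lipogenic genes, 8 rose, or 9 over the list alone (median 0.63, camera adjusted p = 4.7e-04, and adjusted p = 0.21 with an estimated correlation), among them Pltp (2.22 ± 0.18), Lpcat3 (1.48 ± 0.14) and the cholesterol exporter gene Abcg1 (1.21 ± 0.10). Of 26 genes of oxidative phosphorylation, 12 fell and 1 rose, or 13 and 1 over the list alone (median -0.21, camera adjusted p = 1.4e-04, and adjusted p = 0.44 with an estimated correlation), with Ndufb5 at -0.53 ± 0.08. Without Ly6Chi rosiglitazone replicate 3 the median was -0.31, with 17 lower and none higher, and without replicate 2 it was -0.12.

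In rosiglitazone mice 15 of 16 Ly6Clo markers rose (median 2.36, camera adjusted p = 2.0e-17) and all 10 Ly6Chi markers fell (median -2.88, camera adjusted p = 2.5e-13), and both calls held with an estimated correlation (adjusted p = 0.017 and 0.025). Spn was at 2.21 ± 0.17, Itgal at 0.89 ± 0.09, Nr4a1 at 1.27 ± 0.18 and Ccr2 at -2.50 ± 0.15, while Cx3cr1 did not pass (-0.40 ± 0.24, adjusted p = 0.25). All 19 interferon-stimulated genes fell (median -1.05, camera adjusted p = 8.6e-15, and adjusted p = 0.13 with an estimated correlation), among them Usp18 (-2.25 ± 0.15), Mx1 (-1.77 ± 0.16) and Oasl2 (-1.69 ± 0.21). Of 21 adhesion and chemokine receptor genes, 11 rose and 4 fell (median 0.27, camera adjusted p = 0.021, and adjusted p = 0.36 with an estimated correlation), with Pecam1 at 3.56 ± 0.18. Circadian and glucocorticoid-responsive genes had 5 of 14 members higher and none lower, or 5 and 1 over the list alone (median 0.27, camera adjusted p = 0.028, and adjusted p = 0.36 with an estimated correlation). Of 21 cell cycle genes, 11 rose and 3 fell (median 0.37, camera adjusted p = 0.049, and adjusted p = 0.14 with an estimated correlation), with Mcm6 at 1.68 ± 0.14 and the proliferation marker gene Mki67 at -1.24 ± 0.14. Of 11 neutrophil markers, 3 fell, or 4 over the list alone (median -0.14, camera adjusted p = 0.038, and adjusted p = 0.33 with an estimated correlation). The neutrophil call was lost without Ly6Chi rosiglitazone replicate 3 (median -0.030, adjusted p = 0.26) or Ly6Clo rosiglitazone replicate 1 (median -0.058, adjusted p = 0.13) and with quantile normalization (median -0.29, adjusted p = 0.10). Without Ly6Clo rosiglitazone replicate 2 its median was -0.39. With the mean of the probe sets of a gene, the circadian call (adjusted p = 0.078) and the cell cycle call (adjusted p = 0.12) were lost. The cell cycle call was lost without Ly6Chi control replicate 1 (0.054), Ly6Clo control replicates 1 (0.054), 2 (0.051), 3 (0.054) or 4 (0.051), Ly6Chi rosiglitazone replicates 1 (0.20) or 2 (0.085), or Ly6Clo rosiglitazone replicates 1 (0.058) or 3 (0.079), each an adjusted p.

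The subset differences ran alike in the 2 treatments. Across 12104 genes the log2 fold changes between subsets in control and in rosiglitazone mice, which share no arrays, correlated with r = 0.873 (Spearman 0.734). Without the replicate that stood apart, r was 0.896. There were 931 genes higher in Ly6Clo monocytes in both treatments, where 171.6 were expected by chance. A further 1066 genes were lower in both, where 172.7 were expected, and 8 changed in opposite directions. The chance counts take the 2 contrasts as independent, while same-numbered Ly6Chi arrays of the treatments correlated (r = 0.22 to 0.36).

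**Figure D2:**
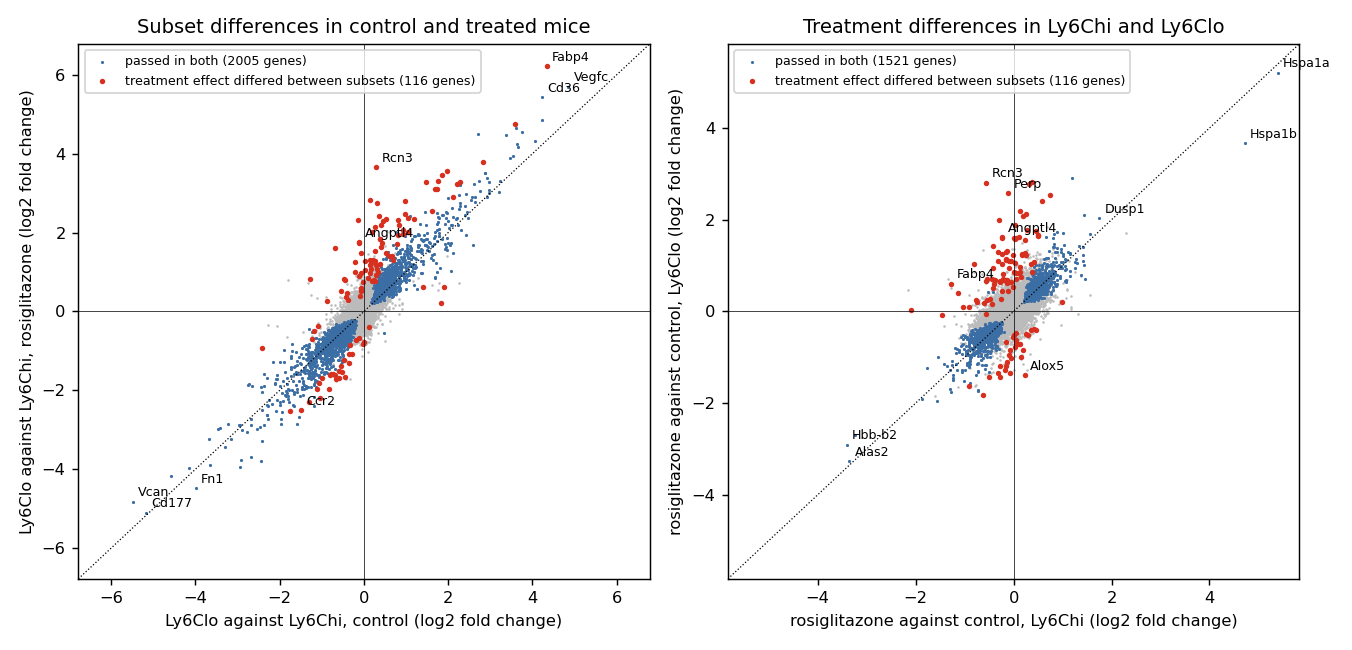
Left, the log2 fold change between Ly6Clo and Ly6Chi monocytes of each gene in control mice against that in rosiglitazone mice (r = 0.873). Right, the log2 fold change with rosiglitazone in Ly6Chi against that in Ly6Clo monocytes (r = 0.703).

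The next comparison asked what changed with rosiglitazone in Ly6Chi monocytes. The heat shock genes Hspa1a (5.39 ± 0.85, adjusted p = 0.0012, 3 treated and 4 control arrays) and Hspa1b (4.72 ± 0.65) had the largest rises, and the phosphatase gene Dusp1 (1.75 ± 0.31), Hmox1, which encodes heme oxygenase 1 (1.57 ± 0.27), and the kinase gene Pim1 (1.42 ± 0.20) were among the next. Hspa1a and Hspa1b are near-identical in sequence, so their probe sets may not tell them apart. The probe sets of Pim1 ranged from -0.27 to 1.42. Among the largest falls were those of the red cell genes Hbb-b2 (-3.41 ± 0.37) and Alas2 (-3.35 ± 0.39), Tent5c (-3.24 ± 0.56), the immunoglobulin genes Ighv14-2 (-2.16 ± 0.42) and Igkv8-30 (-2.10 ± 0.31), the red cell enzyme gene Bpgm (-1.88 ± 0.40), Zfp3 (-1.76 ± 0.18), Kcne3 (-1.55 ± 0.19) and Ear3 (-1.46 ± 0.12). With limma, 2627 genes passed, 992 higher and 1635 lower, of which 45 and 50 changed at least 2-fold, and for 2354 the arrays did not overlap. Without Ly6Chi rosiglitazone replicate 3, 4003 passed, 2308 higher and 1695 lower, with 2179 of the 2627 kept, and without Ly6Chi control replicate 3, 1734 passed. Quantile normalization gave 1715 higher and 1721 lower genes (49.9% higher against 37.8%), and a fit of these 2 groups alone called 785 genes.

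In Ly6Chi monocytes PPAR target genes were lower with rosiglitazone, where 9 of 24 fell and none rose, or 9 and 1 over the list alone (median -0.24, camera adjusted p = 0.048, and adjusted p = 0.90 with an estimated correlation). Fabp4 (-1.27 ± 0.18), Acaa2 (-0.57 ± 0.08), Ech1 (-0.54 ± 0.13) and Cpt1a (-0.54 ± 0.09) fell, the last 3 being genes of fatty acid oxidation. The 4 probe sets of Fabp4 ranged from -1.27 to 0.49. Cd36 (-0.53 ± 0.35, adjusted p = 0.30), Angptl4 (-0.23 ± 0.14, adjusted p = 0.26), Plin2 (-0.24 ± 0.10, adjusted p = 0.10) and Pparg (-0.57 ± 0.22, adjusted p = 0.081) did not pass. The list call was lost with quantile normalization (adjusted p = 0.058). It was also lost without Ly6Chi control replicate 4 (0.056), Ly6Clo control replicates 3 (0.052) or 4 (0.052), Ly6Chi rosiglitazone replicates 1 (0.071), 2 (0.098) or 3 (0.14), or Ly6Clo rosiglitazone replicate 1 (0.051), each an adjusted p. The receptor genes Rxra (-0.90 ± 0.12) and Nr1h3, which encodes LXRα (-0.92 ± 0.15), fell. Their list, PPAR, RXR and coregulators, was not called, with 2 of 13 higher and 2 lower, or 3 and 4 over the list alone (median -0.05, camera adjusted p = 0.86). LXR target and lipogenic genes were not called either, with 4 of 14 higher and 1 lower, or 5 and 1 over the list alone (median 0.12, camera adjusted p = 0.22). Srebf1 (0.65 ± 0.10) and Acaca (0.61 ± 0.10) were among the higher.

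Of 21 immediate early and heat shock genes, 7 rose in Ly6Chi monocytes, or 8 over the list alone (median 0.24, camera adjusted p = 0.0049, and adjusted p = 0.90 with an estimated correlation), with Jund at 1.15 ± 0.15 and Nr4a1 not passing (0.02 ± 0.16, adjusted p = 0.95). Of 19 inflammatory and NF-kB genes, 5 rose and 1 fell, or 6 and 1 over the list alone (median 0.35, camera adjusted p = 0.0081, and adjusted p = 0.10 with an estimated correlation), among them Nfkbia, which encodes an inhibitor of NF-kB (0.71 ± 0.10), Cxcl1 (0.48 ± 0.10) and Icam1 (0.45 ± 0.10). The chemokine receptor gene Cxcr4 rose by 1.27 ± 0.17. Its list, adhesion and chemokine receptors, was not called, with 3 of 21 higher and 5 lower, or 3 and 7 over the list alone (median -0.14, camera adjusted p = 0.57). The immediate early and the inflammatory list moved on arrays whose spikes and Actb values also differed from control, as given above. Of 26 genes of oxidative phosphorylation, 9 fell, or 10 over the list alone (median -0.14, camera adjusted p = 0.031, and adjusted p = 0.90 with an estimated correlation), among them Atp5o (-0.51 ± 0.09) and Ndufs3 (-0.63 ± 0.11). Of 5 red cell markers, 3 fell, or 4 over the list alone (median -1.60, camera adjusted p = 0.010, and adjusted p = 0.90 with an estimated correlation), namely Hbb-b2, Alas2 and Car2 (-1.18 ± 0.37, adjusted p = 0.036), while Slc4a1 did not pass (-1.60 ± 0.59, adjusted p = 0.069). The B cell marker Cd79b fell (-1.42 ± 0.23). The B cell list was not called, with 2 of 8 lower, or 3 over the list alone (median -0.35, camera adjusted p = 0.37). Of the subset markers, Spn (-0.62 ± 0.16) and Treml4 (-0.61 ± 0.09) fell, Itgal rose (0.29 ± 0.09, adjusted p = 0.029), and Ccr2 (-0.33 ± 0.14, adjusted p = 0.12) and Cx3cr1 (-0.27 ± 0.22, adjusted p = 0.41) did not pass.

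Several of these calls in Ly6Chi monocytes were lost when 1 array was left out. Without Ly6Chi rosiglitazone replicate 3, the median was 0.12 for the immediate early and heat shock list (adjusted p = 0.39) and -0.067 for oxidative phosphorylation (adjusted p = 0.14), while the inflammatory list, at 0.40, was not smaller (adjusted p = 0.085). Without replicate 2 the medians of the first 2 were 0.35 and -0.24. Without Ly6Chi rosiglitazone replicate 1, the median was -0.17 for oxidative phosphorylation (adjusted p = 0.11), which was also lost with quantile normalization (median -0.093, adjusted p = 0.058), and -1.33 for the red cell markers (adjusted p = 0.082). Itgal was lost without Ly6Chi control replicates 1 (0.059), 2 (0.054) or 3 (0.085) or Ly6Chi rosiglitazone replicates 1 (0.084) or 2 (0.059), all adjusted p, at log2 fold changes of 0.24 to 0.30, and its direction turned with the mean of its probe sets (-0.017, adjusted p = 0.94). Car2 was lost without Ly6Chi control replicates 1 (0.098), 2 (0.068) or 3 (0.074) or Ly6Chi rosiglitazone replicate 1 (0.094), again as adjusted p, at log2 fold changes of -1.17 to -0.95. Cxcl1 was lost with the mean of its probe sets (adjusted p = 0.063).

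In Ly6Clo monocytes, the comparison of rosiglitazone with control again gave Hspa1a (5.20 ± 0.85, adjusted p = 8.3e-04, 3 treated and 4 control arrays) and Hspa1b (3.66 ± 0.65) as the largest rises, followed by the immediate early gene Fos (2.91 ± 0.32). Others among the largest were Abhd3 (2.82 ± 0.15), Rcn3 (2.81 ± 0.15), Sec16b (2.77 ± 0.11), Perp (2.58 ± 0.09), Shtn1 (2.40 ± 0.24) and Rgs1 (2.19 ± 0.30). Among the largest falls were those of Alas2 (-3.26 ± 0.39), Hbb-b2 (-2.91 ± 0.37), Tent5c (-2.70 ± 0.56), Maneal (-1.96 ± 0.23), Bpgm (-1.90 ± 0.40), Aif1 (-1.82 ± 0.18), the protease gene Lgmn (-1.73 ± 0.16), the oxysterol receptor gene Gpr183 (-1.73 ± 0.18) and Saa2 (-1.70 ± 0.19). Abhd3 (4.64), Sec16b (5.15) and Perp (4.98) in control and Maneal (5.45) and Saa2 (5.23) in treated Ly6Clo monocytes lay under the lower quartile of the arrays. Their differences are bounds of at least 1.87, 2.32 and 1.96 and at most -1.72 and -1.31. With limma, 2986 genes passed, 1711 higher and 1275 lower, of which 141 and 80 changed at least 2-fold, and for 2916 the arrays did not overlap. Without the replicate that stood apart, 5041 passed, 2945 higher and 2096 lower, and all 2986 were among them. Without Ly6Clo rosiglitazone replicate 1, 1852 passed, and without replicate 3, 1968. Median centring gave 1587 higher and 1845 lower genes (46.2% higher against 57.3%), and a fit of these 2 groups alone called 4880 genes.

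PPAR target genes were higher with rosiglitazone in Ly6Clo monocytes, where 11 of 24 rose and none fell, or 14 over the list alone (median 0.42, camera adjusted p = 2.8e-04, and adjusted p = 0.46 with an estimated correlation). Fabp5 (1.76 ± 0.16), Angptl4 (1.62 ± 0.14), Plin2 (1.03 ± 0.10) and Acaa2 (0.66 ± 0.08) were among them, and Fabp4 rose by 0.60 ± 0.18, adjusted p = 0.029. The call of Fabp4 was lost without any 1 of the 7 Ly6Clo arrays (adjusted p = 0.052 to 0.0998, log2 fold change 0.55 to 0.66). With all 14 arrays its 4 probe sets each passed when tested singly, at 0.60 to 1.22. Cd36 (0.67 ± 0.35, adjusted p = 0.18), Cpt1a (0.26 ± 0.09, adjusted p = 0.054) and Pparg (-0.53 ± 0.22, adjusted p = 0.098) did not pass. Yet control and treated Ly6Clo arrays did not overlap for these genes or Fabp4. They lay at 12.4 to 12.5 and 12.9 to 13.1 for Fabp4, and 12.4 to 12.7 and 13.1 to 13.3 for Cd36. They lay at 11.2 to 11.5 and 11.6 to 11.7 for Cpt1a, and at 10.7 to 10.9 and 10.1 to 10.5 for Pparg. The SD of Cd36 was 0.67 and 0.83 in control and treated Ly6Chi and 0.15 and 0.09 in Ly6Clo monocytes. For Fabp4 it was 0.34, 0.42, 0.02 and 0.11, and the error rests on both subsets. With the mean of its probe sets Cd36 did pass (1.16, adjusted p = 0.012). Its 3 probe sets ranged from 0.67 to 1.84, of which 1 passed when tested by itself. Of 14 LXR target and lipogenic genes, 7 rose and 1 fell, or 9 and 3 over the list alone (median 0.44, camera adjusted p = 0.027, and adjusted p = 0.55 with an estimated correlation). Srebf1 (0.72 ± 0.10), Abcg1 (0.68 ± 0.09) and Acaca (0.64 ± 0.10) rose and Apoc2 fell (-1.33 ± 0.14), and the list call was lost without Ly6Clo rosiglitazone replicate 2 (adjusted p = 0.067).

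Among the subset markers in Ly6Clo monocytes, Ccr2 (-1.33 ± 0.14) and Cx3cr1 (-0.97 ± 0.22, adjusted p = 0.0075) fell with rosiglitazone. Adhesion and chemokine receptor genes went both ways. The list was not called, with 5 of 21 higher and 6 lower, or 7 and 7 over the list alone (median -0.02, camera adjusted p = 0.71). Pecam1 (1.60 ± 0.16), Itgb3 (1.32 ± 0.20) and Itgax (0.79 ± 0.14) were among the higher, and Ccr2 and Cx3cr1 among the lower. Nr4a1 (0.36 ± 0.16, adjusted p = 0.12), Spn (-0.15 ± 0.16, adjusted p = 0.53) and Itgal (0.23 ± 0.09, adjusted p = 0.071) did not pass. Of 13 genes of MHC class II and costimulation, 5 fell, or 7 over the list alone (median -0.36, camera adjusted p = 0.0023, and adjusted p = 0.46 with an estimated correlation), among them H2-DMa (-0.82 ± 0.09) and Cd86 (-1.02 ± 0.16). The mean of the dendritic cell markers, a list that was not called, was also lower, at 8.38 to 8.53 on treated and 8.68 to 8.91 on control Ly6Clo arrays. Of 14 scavenger, Fc and efferocytosis receptor genes, 8 fell and 1 rose, or 9 and 1 over the list alone (median -0.59, camera adjusted p = 0.0067, and adjusted p = 0.55 with an estimated correlation). The Fc receptor genes Fcgr1 (-0.87 ± 0.17) and Fcgr3 (-0.57 ± 0.10) fell and Scarb1 rose (0.51 ± 0.08). Of 26 genes of oxidative phosphorylation, 9 fell and 1 rose (median -0.15, camera adjusted p = 0.0019, and adjusted p = 0.59 with an estimated correlation), with Atp5o at -0.64 ± 0.09, Sdhc at -0.43 ± 0.08 and Cox6c at -0.40 ± 0.08.

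Immediate early and heat shock genes had 8 of 21 members higher in treated Ly6Clo monocytes, or 9 over the list alone (median 0.36, camera adjusted p = 0.0025, and adjusted p = 0.59 with an estimated correlation), with Dusp1 at 2.03 ± 0.31 and Jund at 0.89 ± 0.15. Of 5 red cell markers, 4 fell (median -1.85, camera adjusted p = 0.0019, and adjusted p = 0.46 with an estimated correlation), namely Alas2, Hbb-b2, Car2 (-1.15 ± 0.37, adjusted p = 0.035) and Slc4a1 (-1.85 ± 0.59, adjusted p = 0.035). Both lists moved together with the spikes and with the Actb values of the treated arrays. Car2 was lost without Ly6Clo control replicates 1 (0.10), 2 (0.073) or 4 (0.091) or Ly6Clo rosiglitazone replicates 1 (0.11), 2 (0.057) or 3 (0.11), each an adjusted p, at log2 fold changes of -1.28 to -0.93. Slc4a1 was lost without Ly6Clo control replicates 1 (0.09998), 2 (0.055) or 4 (0.086) or Ly6Clo rosiglitazone replicates 1 (0.11) or 3 (0.13), also adjusted p, at log2 fold changes of -1.93 to -1.45. Of 13 T and NK cell markers, 4 fell and 1 rose, or 5 and 1 over the list alone (median -0.36, camera adjusted p = 0.047, and adjusted p = 0.55 with an estimated correlation), with Nkg7 at -0.83 ± 0.18. That call was lost without Ly6Clo control replicates 1 (0.091) or 4 (0.057), Ly6Chi rosiglitazone replicate 2 (0.053) or Ly6Clo rosiglitazone replicate 2 (0.13), again as adjusted p, at medians of -0.36 to -0.24.

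Averaged over both subsets, among the genes that rose most with rosiglitazone were Hspa1a (5.30 ± 0.60, adjusted p = 2.6e-05, 6 treated and 8 control arrays), Hspa1b (4.19 ± 0.46), Fos (2.05 ± 0.22), Dusp1 (1.89 ± 0.22), Hmox1 (1.63 ± 0.19) and Sec16b (1.54 ± 0.08, or 1.19 with values under an array's lower quartile raised to it). The 4 that fell most were Alas2 (-3.31 ± 0.28), Hbb-b2 (-3.16 ± 0.26), Tent5c (-2.97 ± 0.40) and Bpgm (-1.89 ± 0.28). Pparg fell by 0.55 ± 0.16 on the log2 scale (adjusted p = 0.013). Angptl4 (0.69 ± 0.10) and Plin2 (0.40 ± 0.07) rose, while Fabp4 (-0.34 ± 0.13, adjusted p = 0.054), Cpt1a (-0.14 ± 0.06, adjusted p = 0.097) and Cd36 (0.07 ± 0.25, adjusted p = 0.85) did not pass. The direction of Fabp4 was unsettled, since it passed at -0.35 with quantile normalization (adjusted p = 0.035) and at 0.24 with the mean of its probe sets (adjusted p = 0.028). Cpt1a passed with the mean of its probe sets (-0.48, adjusted p = 0.023). Cxcr4 (1.21 ± 0.12) rose, as did the clock gene Per1 (0.91 ± 0.20) and the glucocorticoid-induced kinase gene Sgk1 (0.83 ± 0.13), and Per3 fell (-0.70 ± 0.09). Their lists were not called. There were 7 of 21 adhesion and chemokine receptor genes higher and 9 lower (median -0.13, camera adjusted p = 0.66). A further 4 of 14 circadian and glucocorticoid-responsive genes were higher and 1 lower (median 0.10, camera adjusted p = 0.66). In limma, 4821 genes passed, 2423 higher and 2398 lower, of which 67 and 45 changed at least 2-fold, and for 2090 the arrays did not overlap in either subset. Without the replicate that stood apart, 6482 passed, 3711 higher and 2771 lower, with 4692 of the 4821 kept.

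In this average, LXR target and lipogenic genes (7 of 14 higher and 1 lower, median 0.27, camera adjusted p = 0.040, and adjusted p = 0.80 with an estimated correlation) were called up, with Srebf1 at 0.69 ± 0.07 and Acaca at 0.63 ± 0.07. Immediate early and heat shock genes (8 of 21 higher, median 0.26, camera adjusted p = 0.0047, and adjusted p = 0.80 with an estimated correlation) were called up as well. Called down were oxidative phosphorylation (12 of 26 lower and 1 higher, median -0.14, camera adjusted p = 0.0047, and adjusted p = 0.86 with an estimated correlation), with Atp5o at -0.57 ± 0.06 and Ndufs3 at -0.57 ± 0.07, and MHC class II and costimulation (6 of 13 lower, median -0.23, camera adjusted p = 0.016, and adjusted p = 0.80 with an estimated correlation), with H2-DMa at -0.57 ± 0.06. With single arrays left out the MHC class II median ranged from -0.32 to -0.14. Red cell markers were also called down (4 of 5 lower, median -1.73, camera adjusted p = 0.0047, and adjusted p = 0.80 with an estimated correlation). The LXR call was lost without Ly6Chi rosiglitazone replicates 1 (0.059) or 3 (0.079) or Ly6Clo rosiglitazone replicate 2 (0.079), and the immediate early and heat shock call without Ly6Chi rosiglitazone replicate 3 (0.11), each an adjusted p. With the mean of the probe sets of a gene, the LXR list had a median of 0.17 (adjusted p = 0.064). Across genes the log2 fold changes with rosiglitazone in the 2 subsets, which share no arrays, correlated with r = 0.703 (Spearman 0.693), or 0.766 without the replicate that stood apart. There were 681 genes higher in both subsets, where 140.2 were expected by chance, 822 lower in both, where 172.2 were expected, and 18 that changed in opposite directions. Because the treated arrays of both subsets also shared lower spikes, batch and treatment cannot be told apart in this overlap. The chance counts take the 2 contrasts as independent, while same-numbered treated arrays of the subsets correlated (r = 0.13 to 0.33).

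**Figure D3:**
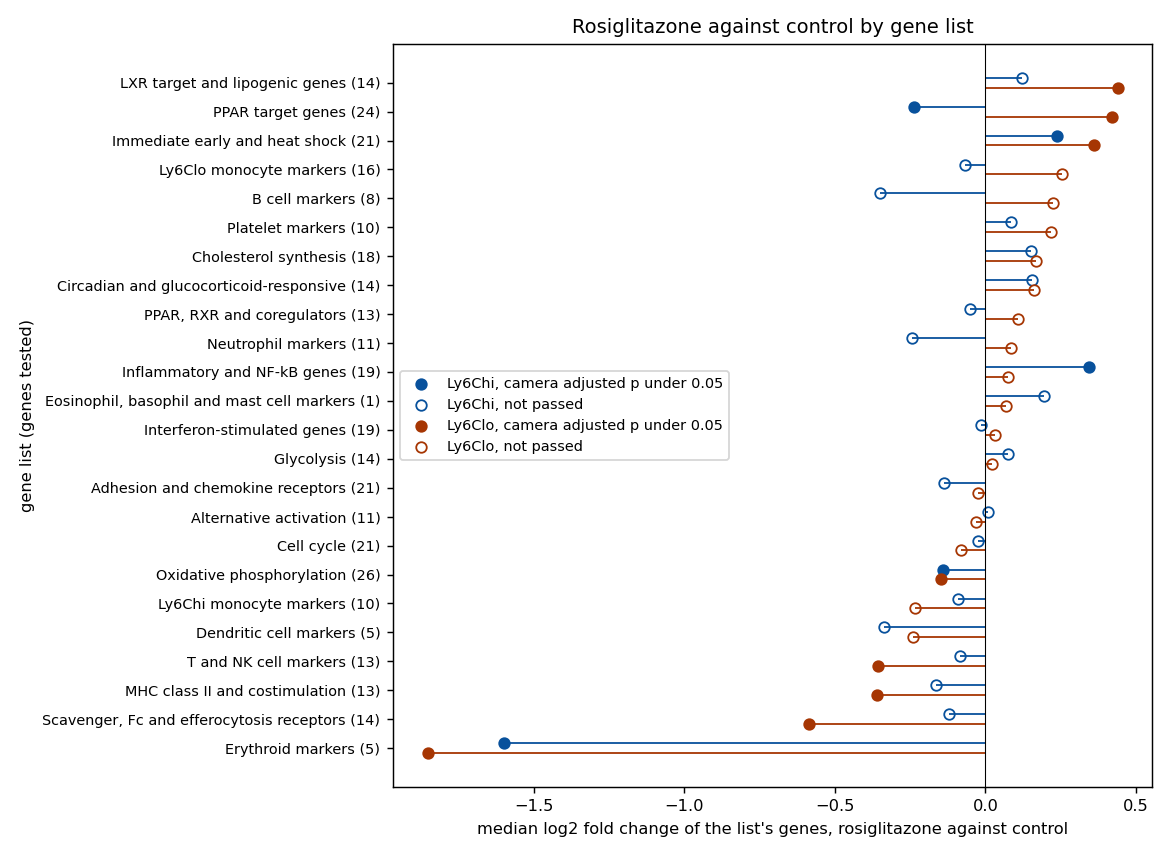
Median log2 fold change with rosiglitazone of each gene list in Ly6Chi and in Ly6Clo monocytes. PPAR target genes lay at -0.24 in Ly6Chi and at 0.42 in Ly6Clo monocytes.

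The last comparison tested whether the effect of rosiglitazone differed between the subsets, given as the effect in Ly6Clo minus that in Ly6Chi monocytes, in which a shift common to both subsets cancels and an unequal one does not. The shift of the treated arrays was unequal in some measures, with a change in the poly-A spikes of -3.53 in Ly6Chi and -2.45 in Ly6Clo monocytes. The 3-prime minus 5-prime value changed by 0.10 and 0.28 for Gapdh and by 0.16 and 0.39 for Actb, and the hybridization spikes by -2.23 and -1.98. Processing and drug are therefore not fully parted in this contrast either. Among the largest positive differences were those of Rcn3 (3.37 ± 0.21, adjusted p = 1.2e-06), Perp (2.69 ± 0.13), Sec16b (2.46 ± 0.16), Abhd3 (2.44 ± 0.21), the retinal reductase gene Dhrs3 (2.29 ± 0.39) and Fabp4 (1.88 ± 0.26, adjusted p = 0.0017). Perp, Sec16b and Abhd3 lay under the lower quartile of the arrays in all groups but treated Ly6Clo monocytes, so any change in Ly6Chi monocytes was not measured, and with values under an array's lower quartile raised to it their differences were 1.92, 2.26 and 1.83. Among the largest negative differences were those of Alox5, which encodes 5-lipoxygenase (-1.62 ± 0.20, adjusted p = 6.4e-04), Slamf9 (-1.27 ± 0.15), S100a6 (-1.15 ± 0.13), Emb (-1.13 ± 0.16), Crip1 (-1.10 ± 0.14), S100a4 (-1.02 ± 0.11) and Ccr2 (-1.01 ± 0.20, adjusted p = 0.031). With limma, 116 genes passed, 85 with a higher and 31 with a lower effect in Ly6Clo monocytes, of which 54 and 9 differed at least 2-fold. Of the 85, 56 rose in Ly6Clo monocytes and did not pass in Ly6Chi, 13 rose in Ly6Clo and fell in Ly6Chi, 10 fell in Ly6Chi and did not pass in Ly6Clo, and 6 rose in both. Of the 31, 23 fell in Ly6Clo and did not pass in Ly6Chi. In control mice 40 of the 85 were higher and 12 lower in Ly6Clo than in Ly6Chi monocytes, and 3 of the 31 were higher and 21 lower. Without Ly6Chi rosiglitazone replicate 3, 204 genes passed, 116 higher and 88 lower, with all 116 kept, and the count was 74 without Ly6Chi control replicate 2, 77 without Ly6Chi control replicate 3, 74 without Ly6Clo control replicate 4 and 68 without Ly6Clo rosiglitazone replicate 1. Quantile normalization gave 118 higher and 71 lower genes (62.4% higher against 73.3%), and median centring gave 91 and 65 (58.3%) and moved the median of all genes from 0.08 to -0.02.

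PPAR target genes had a higher change with rosiglitazone in Ly6Clo than in Ly6Chi monocytes, with list medians of 0.42 and -0.24. Of 24, 8 had a higher effect and none a lower, or 12 over the list alone (median 0.58, camera adjusted p = 4.3e-16). This call held with an estimated correlation (adjusted p = 0.0045) and without the replicate that stood apart (median 0.38, adjusted p = 1.3e-16). The 4 probe sets of Fabp4 ranged from 0.73 to 1.88, of which 1 passed when tested by itself. Besides Fabp4, members of the list included Angptl4 (1.85 ± 0.20, adjusted p = 3.1e-04), Plin2 (1.27 ± 0.14), Acaa2 (1.23 ± 0.12), the carnitine carrier gene Slc25a20 (1.05 ± 0.14) and Cpt1a (0.80 ± 0.13, adjusted p = 0.0062). With the mean of its probe sets the call of Cpt1a was lost (adjusted p = 0.20). Cd36 did not pass (1.20 ± 0.50, adjusted p = 0.45), and its 3 probe sets ranged from 1.20 to 1.68, of which 1 passed when tested by itself. Pparg did not pass either (0.04 ± 0.31, adjusted p = 0.97). The cholesterol exporter gene Abcg1, an LXR target, had a higher effect as well (0.84 ± 0.13). The LXR list was not called, with 2 of 14 higher and 0 lower, or 4 and 3 over the list alone (median 0.14, camera adjusted p = 0.62).

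**Figure D4:**
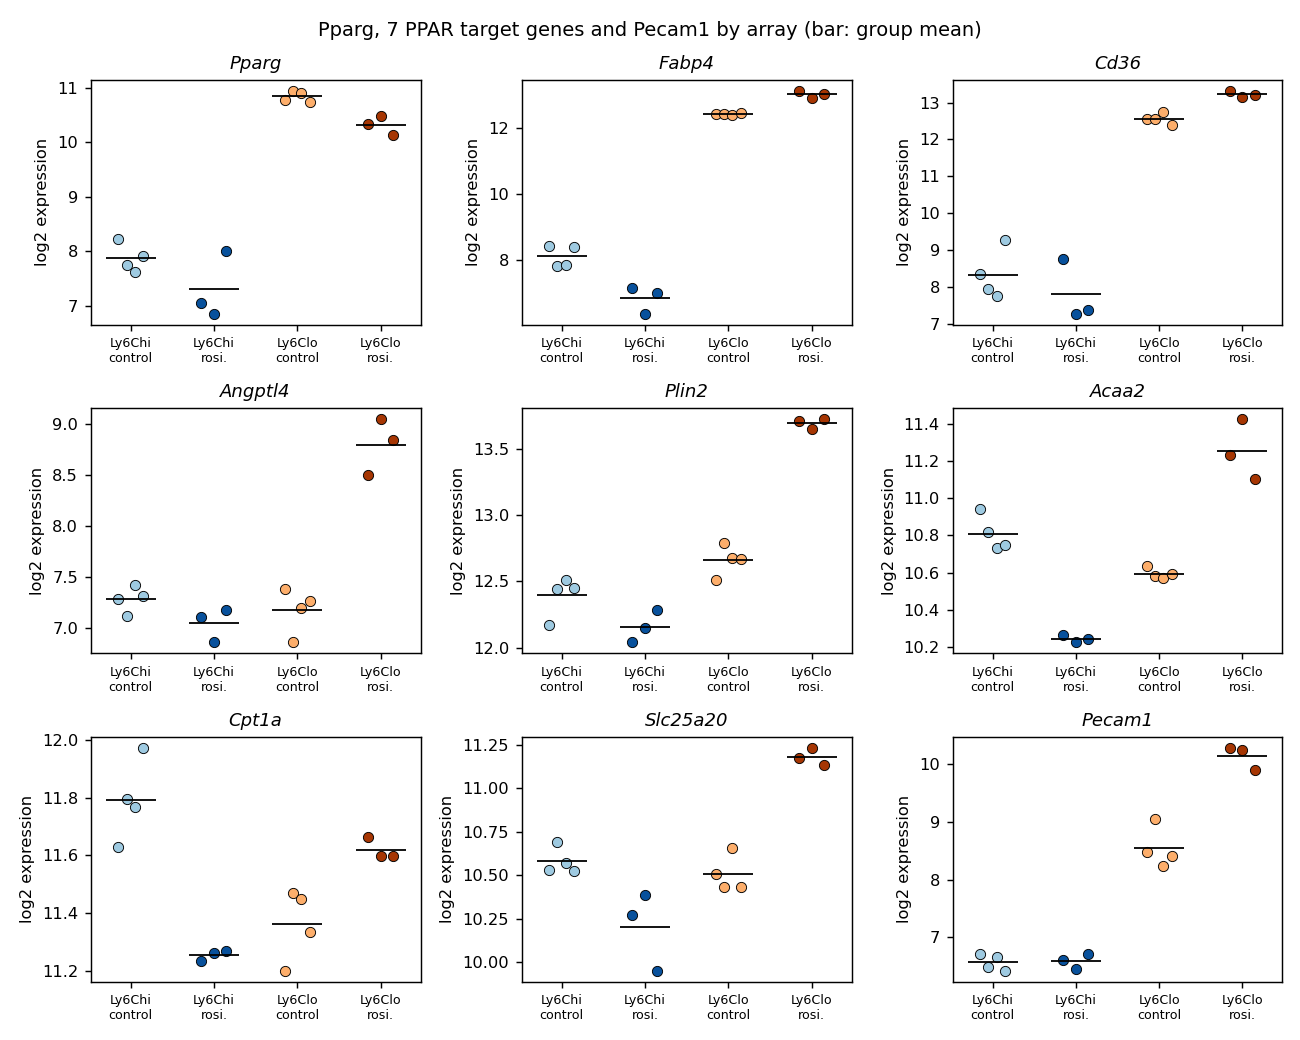
Log2 expression of 9 genes on each of the 14 arrays, by subset and treatment, with group means. Angptl4 and Plin2 were higher in treated than in control Ly6Clo monocytes, by 1.62 and 1.03.

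Inflammatory and NF-kB genes had a lower effect of rosiglitazone in Ly6Clo than in Ly6Chi monocytes, with 1 of 19 passing, or 2 over the list alone (median -0.35, camera adjusted p = 1.7e-05). That call held with an estimated correlation (adjusted p = 0.0045) and without the replicate that stood apart (adjusted p = 4.2e-04), while without Ly6Clo rosiglitazone replicate 2 the median was -0.20. The inflammasome gene Nlrp3 was the member that passed (-0.80 ± 0.14, adjusted p = 0.011), while Tlr2 (-0.62 ± 0.18, adjusted p = 0.18) and Il1b (-0.83 ± 0.38, adjusted p = 0.53) did not. Ly6Clo markers were called up (1 of 16 higher, or 5 over the list alone, median 0.47, camera adjusted p = 6.6e-04, and adjusted p = 0.40 with an estimated correlation), with Treml4 at 0.78 ± 0.12. Pecam1, an adhesion gene, was at 1.59 ± 0.23. Its list was not called, with 2 of 21 higher and 1 lower, or 3 and 1 over the list alone (median -0.02, mean 0.13, test direction up, camera adjusted p = 0.97). Among the other subset markers, Cx3cr1 (-0.69 ± 0.32, adjusted p = 0.52), Nr4a1 (0.34 ± 0.23, adjusted p = 0.69), Spn (0.47 ± 0.22, adjusted p = 0.53) and Itgal (-0.07 ± 0.12, adjusted p = 0.87) did not pass. Scavenger, Fc and efferocytosis receptors were called down with no member passing, or 4 lower and 1 higher over the list alone (median -0.44, camera adjusted p = 0.0015, and adjusted p = 0.40 with an estimated correlation). MHC class II and costimulation was called down with no member passing, or 1 over the list alone (median -0.18, camera adjusted p = 0.013, and adjusted p = 0.42 with an estimated correlation). Markers of other cells moved too, with B cell markers up (1 of 8, or 4 higher and 1 lower over the list alone, median 0.75, camera adjusted p = 0.049, and adjusted p = 0.58 with an estimated correlation), with Cd22 at 1.83 ± 0.29. T and NK cell markers were called down with no member passing (median -0.13, camera adjusted p = 0.011, and adjusted p = 0.40 with an estimated correlation).

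Some calls in this difference between subsets were lost when 1 array was left out. The MHC class II call was lost without Ly6Chi control replicate 3 (0.050), Ly6Chi rosiglitazone replicate 1 (0.15) or Ly6Clo rosiglitazone replicate 1 (0.053), each an adjusted p, at medians of -0.075 to -0.060. The T and NK cell call was lost without Ly6Clo control replicate 1 (0.061) or Ly6Chi rosiglitazone replicate 3 (0.10), also adjusted p, at medians of -0.099 and -0.14, and its median ranged from -0.31 to -0.048 over all arrays left out. The B cell call was lost without Ly6Chi control replicates 1 (0.10), 3 (0.052) or 4 (0.053), Ly6Clo control replicates 2 (0.12) or 4 (0.067), Ly6Chi rosiglitazone replicates 1 (0.15) or 2 (0.13), or Ly6Clo rosiglitazone replicate 1 (0.081), again as adjusted p, at medians of 0.61 to 0.84. With quantile normalization these 3 lists had adjusted p = 0.070, 0.066 and 0.058, and without the filter the T and NK cell list had adjusted p = 0.10. Ccr2 was lost without Ly6Chi control replicates 1 (0.064), 2 (0.066), 3 (0.051) or 4 (0.073), Ly6Clo control replicates 1 (0.065), 2 (0.064) or 4 (0.066), Ly6Chi rosiglitazone replicates 1 (0.064) or 2 (0.066), or Ly6Clo rosiglitazone replicates 1 (0.066) or 2 (0.068), all adjusted p, at differences of -1.04 to -0.83. Ccr2 was also lost with the mean of its probe sets (-0.86, adjusted p = 0.14) and with the replicate number as a block (adjusted p = 0.055), under which Il1b passed (adjusted p = 0.025).

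Of the 24 gene lists, 6 were called in no comparison of the main fit. Glycolysis genes in control mice had 4 of 14 members higher and 4 lower in Ly6Clo monocytes (median 0.09, camera adjusted p = 0.64). Alternative activation genes had 3 of 11 higher and 2 lower (median -0.12, mean 0.07, test direction up, camera adjusted p = 0.64). The list of PPAR, RXR and coregulator genes had 4 of 13 higher and 2 lower (median 0.01, camera adjusted p = 0.49). No member of 10 platelet markers passed between the subsets (median 0.24, camera adjusted p = 0.38). Dendritic cell markers had 1 of 5 higher and 2 lower (median 0.08, mean -0.05, test direction down, camera adjusted p = 0.94). The list of eosinophil, basophil and mast cell markers had 1 tested member, which did not pass (0.15, camera adjusted p = 0.64). With rosiglitazone in Ly6Clo monocytes, camera adjusted p was 0.81 for glycolysis, 0.22 for alternative activation, 0.89 for PPAR, RXR and coregulators, 0.51 for platelet, 0.15 for dendritic cell and 0.89 for eosinophil, basophil and mast cell markers. In Ly6Chi monocytes these values were 0.78, 0.97, 0.86, 0.57, 0.57 and 0.62. Between the subsets in rosiglitazone mice they were 0.95, 0.95, 0.77, 0.52, 0.58 and 0.96, and on average 0.91, 0.51, 0.91, 0.44, 0.39 and 0.66. For the difference of the rosiglitazone effect they were 0.36, 0.098, 0.86, 0.97, 0.50 and 0.54. There the alternative activation list (median -0.03) was called without Ly6Chi control replicate 4 (0.043), Ly6Clo control replicate 3 (0.037), Ly6Chi rosiglitazone replicate 2 (0.042) or Ly6Clo rosiglitazone replicate 2 (0.011), each an adjusted p, at medians of -0.34 to -0.0047. The eosinophil, basophil and mast cell list was called with no filter (adjusted p = 0.018).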

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

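Of the tests in this part, 3 were chosen only after the result was seen: that of a shift common to both subsets, that of the spikes and 3-prime minus 5-prime values by subset, and that of the signal range of the array that stood apart.

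The first pattern is that PPAR target genes were called up with rosiglitazone in Ly6Clo and not in Ly6Chi monocytes. In Ly6Chi they were called down (median -0.24, camera adjusted p = 0.048, and 0.90 with an estimated correlation), so a fall there is part of the difference. With an estimated correlation the call in Ly6Clo was lost (adjusted p = 0.46) and that of the difference held (adjusted p = 0.0045). Distortion by Ly6Chi rosiglitazone replicate 3 is argued against, since without that array the list median of the difference was 0.38. A shift of all treated arrays that is common to both subsets would cancel, and the median was 0.58. The treated arrays did not shift alike in both subsets in all measures, however. From control to treated, the poly-A spikes changed by -3.53 in Ly6Chi and -2.45 in Ly6Clo monocytes (difference ± standard error 1.09 ± 0.42), the 3-prime minus 5-prime value of Gapdh by 0.10 and 0.28 (0.19 ± 0.07) and that of Actb by 0.16 and 0.39 (0.24 ± 0.12). The hybridization spikes changed by -2.23 and -1.98 (0.25 ± 0.39). Genes that are brighter in Ly6Clo monocytes might respond more, but the list median lay at percentile 100 of 10000 random lists matched on level and subset difference, whose medians had a median of 0.084 and a highest value of 0.27. Members of the random lists were drawn independently, so the spread of their medians may be too narrow. The matching also used control arrays that enter the difference. A subset-specific response to the drug stays open as a hypothesis, found and tested on the same data, as does a processing difference that acts on the subsets unequally, which these values leave open and whose effect on the list was not tested.

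The second pattern is that the red cell list was called down and the immediate early and heat shock list up with rosiglitazone in both subsets at the preset correlation. None of these calls held with an estimated correlation (adjusted p = 0.90 in Ly6Chi and 0.46 in Ly6Clo for red cell markers, 0.90 and 0.59 for immediate early and heat shock genes). Of the immediate early and heat shock genes 7 and 8 of 21 passed, and without Ly6Chi rosiglitazone replicate 3 their call in Ly6Chi was lost (adjusted p = 0.39). Less red cell RNA in the treated sorts cannot be told apart from other explanations: the higher of the 2 subset medians of 15 further red cell genes was -0.11, and as a set they passed in Ly6Clo and not in Ly6Chi monocytes at the preset correlation and in neither with an estimated one (p = 0.16 in Ly6Clo and 0.63 in Ly6Chi), which keeps it open. Of the 15, 2 fell and 1 rose in Ly6Chi and 3 fell in Ly6Clo. Mkrn1 (-0.78 and -0.92) and Fech (-0.78 and -0.77) fell in both, Nfe2 fell in Ly6Clo alone (-0.30), and Xpo7 rose in Ly6Chi (0.35, adjusted p = 0.021). Treated and control arrays that were hybridized or amplified apart fit the spikes, which differed by -2.11 (exact permutation p = 0.000333, the smallest that 3003 splits can give). An effect of the drug on these genes stays open and untested, since batch and treatment cannot be told apart.

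The third pattern is that Ly6Chi rosiglitazone replicate 3 stands apart from its group. Lower RNA quality is argued against, since its 3-prime minus 5-prime value of Actb was 0.395 among 0.204 to 0.903 on the other arrays, and that of Gapdh 0.187 among -0.03 to 0.416. No marker list of another cell type exceeded both other arrays of the group. The largest excess was -0.0255, for the eosinophil, basophil and mast cell list, which had 1 tested member. The rule asked for over 1 log2 unit, so this argues against a large share of such cells and leaves a small one open. A Ly6Clo pool under a Ly6Chi label is argued against by a Ly6Clo minus Ly6Chi marker value of -2.06, among -2.81 and -1.94 on the other Ly6Chi arrays and far from 2.93 to 3.30 on the Ly6Clo arrays. A compressed signal range fits, with an interquartile range of 2.33 against 2.67 to 2.87 on the other arrays. No biological explanation was tested for this array.

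Refits of the same arrays in other splits asked how often as many genes pass by chance. The true grouping was the 1 split of 35 with the most genes for the subsets in control mice (2688, the highest other 0), for rosiglitazone in Ly6Chi (2627, the highest other 98) and in Ly6Clo monocytes (2986, the highest other 130). It was the 1 of 100 for the average (4821, the highest other 1035) and for the difference between subsets, with the main effects removed first (116, the highest other 2). For the subsets in rosiglitazone mice, 10 splits are too few for a share under 0.05. Among the splits that part every pair, 4 for the subsets in rosiglitazone mice and 8 for rosiglitazone in Ly6Chi monocytes, all others gave 0 genes. These too are too few for a share under 0.05. If the Ly6Chi arrays are paired, the 35 splits do not decide for rosiglitazone in Ly6Chi monocytes.

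A sample lay far from the other 3 of its group, by the share of the group's range that its gap to the nearest array takes, in 17 of 336 groups of values, or 5.06%, and chance does so in about 1 in 20. For Ly6Chi control replicate 1 these were F13a1 (0.955), Cxcl10 (0.853), Ets1 (0.858), Itgb3 (0.840), the neutrophil markers (0.859) and the 3-prime minus 5-prime value of Actb (0.917). For other Ly6Chi control arrays they were Per1 on replicate 3 (0.869) and Ifit1 on replicate 4 (0.847). For Ly6Clo control replicate 1 they were Mcm7 (0.918), Igkv8-30 (0.868) and Ear3 (0.874). For Ly6Clo control replicate 2 they were Csf3r (0.874), Msr1 (0.831), Rgs1 (0.844) and the interquartile range (0.838). Slc12a2 on Ly6Clo control replicate 3 (0.866) and the Ly6Clo markers on Ly6Clo control replicate 4 (0.923) complete them.

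The effect of rosiglitazone differed between the subsets in the limma test of the difference for 116 genes. Among the named genes the difference, Ly6Clo minus Ly6Chi on the log2 scale, was 3.37 for Rcn3, 2.69 for Perp, 2.46 for Sec16b, 2.44 for Abhd3, 2.29 for Dhrs3, 2.12 for Igkv8-30, 2.05 for Rgs1, 1.88 for Fabp4, 1.85 for Angptl4, 1.83 for Cd22, 1.83 for Shtn1, 1.59 for Pecam1, 1.45 for Itgb3, 1.38 for Ear3, 1.30 for Fabp5, 1.27 for Plin2, 1.25 for Ech1, 1.23 for Acaa2, 1.05 for Slc25a20, 0.84 for Abcg1, 0.80 for Cpt1a and 0.78 for Treml4. Those of Perp, Sec16b and Abhd3 are set against groups under the lower quartile of the arrays. The difference was -1.62 for Alox5, -1.27 for Slamf9, -1.19 for Aif1, -1.15 for S100a6, -1.13 for Emb, -1.10 for Crip1, -1.02 for S100a4, -1.01 for Ccr2 and -0.80 for Nlrp3. Among gene lists the median difference was 0.75 for B cell markers, 0.58 for PPAR target genes, 0.47 for Ly6Clo markers, -0.44 for scavenger, Fc and efferocytosis receptors, -0.35 for inflammatory and NF-kB genes, -0.18 for MHC class II and costimulation and -0.13 for T and NK cell markers. With an estimated correlation only the PPAR and inflammatory lists kept the call, and adjusted p was 0.58 for B cell markers, 0.40 for Ly6Clo markers, 0.40 for scavenger receptors, 0.42 for MHC class II and 0.40 for T and NK cell markers. The B cell, MHC class II and T and NK cell calls were also lost without some single arrays, with MHC class II at medians of -0.075 to -0.060.

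Probe sets with no single gene name, which the comparisons do not use, also differed from control. Of 3702 tested, 284 were higher and 435 lower with rosiglitazone in Ly6Chi monocytes, 529 higher and 416 lower in Ly6Clo monocytes, and 17 had a higher and 3 a lower effect in Ly6Clo than in Ly6Chi monocytes.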

How the results depend on the processing

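Of the tests in this part, only the fit with values under an array's lower quartile raised to it was chosen after the data were seen, and where a value changed, the cause was not tested unless said. The 2 agreements between contrasts stayed within 1 standard deviation of replicates with no filter, quantile normalization, the mean of probe sets, the replicate block and each array left out. Of the named pairs of gene and contrast, 220 passed. Of these, 219 did so under the replicate block, 220 with quantile normalization, 214 with the mean of probe sets, 220 with values under the lower quartile raised, and 214 whichever array was left out. Single probe sets were also looked at for some of these genes, and no other alternative was run on them. With every probe set counted by itself, which tests more items, 4578, 5620, 5328, 6388 and 9995 passed for the subsets in control mice, the subsets in rosiglitazone mice, rosiglitazone in Ly6Chi, in Ly6Clo and their average. Array quality weights, whose estimation stopped before its convergence tolerance was reached, gave 4093, 6156, 6518, 6117 and 7898, and 810 for the difference between subsets. A fit of the 2 compared groups alone gave 1544 for the subsets in rosiglitazone mice, 785 in Ly6Chi and 4880 in Ly6Clo. A 2-fold minimum, which removes genes by construction, left 518, 743, 95, 221, 112 and 63. For the difference between subsets, quantile normalization gave 189 and eBayes with trend and robust 179. With the estimated correlation 7 of 47 list calls held and 0 of 9 for other cell types, where quantile normalization kept 5. The PPAR target medians of -0.24 in Ly6Chi and 0.42 in Ly6Clo were no longer called with the estimated correlation (adjusted p = 0.90 and 0.46), nor was -0.22 in Ly6Chi with quantile normalization (0.058). Itgal in Ly6Chi turned from 0.29 to -0.017 with the mean of its probe sets. Named genes that did not pass but did with quantile normalization were Plin2 between subsets in control mice (0.30, adjusted p = 0.026), Cpt1a in Ly6Clo (0.28, 0.044), Itgal in Ly6Clo (0.28, 0.016), Fabp4 on average (-0.35, 0.035) and Tlr2 in the difference (-0.70, 0.027). With the mean of probe sets these were Cd36 in Ly6Clo (1.16, 0.012) and, on average, Fabp4 with the opposite sign (0.24, 0.028) and Cpt1a (-0.48, 0.023).

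Leaving out each array in turn gave 2238 to 3951 genes for the subsets in control mice, 2409 to 3721 in rosiglitazone mice, 1734 to 4003 for rosiglitazone in Ly6Chi, 1852 to 5041 in Ly6Clo, 4056 to 6482 on average and 68 to 204 for the difference. List calls ranged from 40 to 48, and those of other cell types from 6 to 9. The PPAR target median ranged from -0.27 to -0.20 in Ly6Chi, from 0.39 to 0.47 in Ly6Clo and from 0.38 to 0.65 in the difference.

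With the replicate number as a block, 3350 genes passed for the subsets in rosiglitazone mice and 2590 for rosiglitazone in Ly6Chi monocytes. These are the 2 comparisons that the rule took as paired. There 3095 and 2323 of the main calls were kept, and the block changed no other call of a list or named gene. For the subsets in control mice and rosiglitazone in Ly6Clo the arrays share only a number, and the average and the difference take in comparisons of both kinds. Same-numbered arrays correlated with r = 0.26, 0.36, -0.07 and -0.11 for the subsets in control mice and -0.03, 0.20 and 0.03 for rosiglitazone in Ly6Clo, and not every array correlated best with its own number. The block gave 2785 and 2911 genes in these 2, and 4568 for the average and 107 for the difference. It gave the same 47 list calls and 9 for other cell types, and PPAR target medians of -0.22, 0.42 and 0.58. Under the block Plin2 between subsets in control mice (adjusted p = 0.035), Cpt1a in Ly6Clo (0.049) and Il1b in the difference (0.025) passed, and Ccr2 in the difference did not (0.055). The agreements under the block were 0.873 and 0.705. With treatment and replicate number together as a block, which pairs the 2 subsets within a treatment, 2699, 3299, 2632, 2980, 4405 and 109 genes passed in the 6 contrasts.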

Other observations

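Levels of single genes set the scale of the changes above. Perp lay under the lower quartile of the arrays in 3 groups, at 4.84 ± 0.07 (SD, n = 4) in control Ly6Chi, 4.98 ± 0.13 (n = 4) in control Ly6Clo and 4.73 ± 0.03 (n = 3) in treated Ly6Chi monocytes, and stood at 7.56 ± 0.14 (n = 3) in treated Ly6Clo monocytes. Rcn3 stood at 7.32 ± 0.31, 7.61 ± 0.11 and 6.76 ± 0.06 in those groups and at 10.42 ± 0.20 in treated Ly6Clo monocytes. Cd36 was already at 12.6 ± 0.15 in control Ly6Clo monocytes and at 13.2 ± 0.09 in treated ones, and Fabp4 at 12.4 ± 0.02 and 13.04 ± 0.11. The mean over PPAR target genes was 9.41 ± 0.04 in control Ly6Chi, 9.66 ± 0.03 in control Ly6Clo, 9.18 ± 0.16 in treated Ly6Chi and 10.1 ± 0.03 in treated Ly6Clo monocytes.

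Levels of markers of other cell types are means over the members kept by the filter, 5 of 11 for red cells, 10 of 12 for platelets and 8 of 11 for B cells, and do not show that each was detected. The mean log2 level of the red cell markers was 8.90 ± 0.57 (SD, n = 4) in control Ly6Chi and 9.20 ± 0.63 (n = 4) in control Ly6Clo monocytes, and 6.98 ± 0.33 (n = 3) and 7.34 ± 0.20 (n = 3) in the treated ones. Platelet markers lay at 8.87 ± 0.43 and 9.10 ± 0.46 in control and at 8.96 ± 0.31 and 9.37 ± 0.34 in treated Ly6Chi and Ly6Clo monocytes. B cell markers lay at 8.46 ± 0.27 and 8.29 ± 0.24 in control and at 7.98 ± 0.12 and 8.57 ± 0.09 in treated Ly6Chi and Ly6Clo monocytes.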
